A study of Mus musculus with 20 samples.

How the data were processed

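Bulk RNA-seq was measured in cortex of 5xFAD mice, an amyloid model that carries human transgenes with familial Alzheimer's disease mutations. Per the labels, 20 libraries fell into 4 groups of 5: control (wild-type Abca7) and knockin (KI) at 3 and at 10 months of age. The protocol in the labels speaks of male littermates and of heterozygous as well as homozygous knockin animals, and the KI label does not say which of these a library came from. The labels do not state outright that each library is a separate animal, so p-values measure the spread between libraries. Total RNA was extracted with TRIzol and a column kit with DNase and was sequenced on an Illumina HiSeq instrument.

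The authors deposited 1 table of raw counts per gene for all 20 libraries, with gene identifiers, coordinates, symbols and biotypes. The genome build was mm10 per the submitters' processing notes. The aligner, the counting program, its strand setting and the annotation release were not given in the sources used here. The table held 43346 annotated genes, and all 37 mitochondrial genes were 0 in every library, so nothing can be said of mitochondrially encoded transcripts. Library totals ran from 42896149 to 57447015 counts. At that depth, summed over genes, counting error was small beside the spread between replicates. The chi-square per degree of freedom between replicates ran from 10.7 to 120 within groups. That sum is led by genes with many counts, and counting error need not be small for genes with few. Because strand handling is unknown, counts of genes that overlap a neighbour or share sequence with a near-identical copy are uncertain.

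Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed by filterByExpr, which left 19623 genes, and libraries were scaled by TMM (factors 0.972 to 1.03). A quasi-likelihood F test with robust dispersion was fitted to the 4 group means over all 20 libraries (16 residual degrees of freedom), and 6 contrasts were drawn: KI against control at each age, their average, 10 against 3 months in each genotype, and the genotype by age interaction. P-values were adjusted by Benjamini-Hochberg within a contrast, with calls at 0.05. Log2 fold changes are given with their SE from the same model, and expression as CPM (counts scaled to a fixed library total) with the SD over 5 libraries. Values of single genes, and list scores, were compared by 2-sided exact permutation tests over the 252 assignments of 5 against 5 libraries, whose smallest p is 0.0079. Abca7 and members of the gene lists were fixed in advance for this test. Thy1 was not among them, and the sums of counts with pseudogenes were chosen after the calls were seen. A permutation of list scores within each age, over 63504 assignments, was added outside the plan.

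Gene lists for microglial states, inflammation, lipids, organelles, cell types, neighbouring brain regions and sample quality were fixed with the design, together with the rule for named genes, before the data were examined. Of 37 lists, 36 had at least 5 tested members. Each was tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01, beside camera with an estimated correlation and fry, and adjusted over the lists of a contrast. Counts of called members are given over all genes tested and adjusted over the list alone. A list score is the mean over members of log2 CPM (prior count 2) centred per gene.

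The genes named are, per contrast, the 10 higher and 10 lower called genes of largest log2 fold change with a mean of at least 1 CPM, leaving out predicted genes whose symbols are Gm with digits or end in Rik. Where a contrast had fewer than 10 called genes before these filters, the 10 filtered genes of smallest unadjusted p were added as values. Abca7 was named in every contrast, with up to 4 members of smallest p from each list described. Called genotype genes outside this rule were named after their values were seen.

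In libraries with simulated changes in 50 genes per fold, edgeR recovered 12% of genes changed 1.2-fold in the 3 month genotype comparison, 76% at 1.5-fold, 98% at 2-fold and 100% at 4-fold. At 10 months the shares were 16%, 68%, 96% and 98%. For age in control they were 6%, 64%, 88% and 100%, and for age in KI 6%, 66%, 94% and 100%. The changed genes all had a mean of at least 1 CPM, so these shares do not cover genes of lower level. Genes were drawn independently, so spread that genes share between libraries was not simulated. The averaged and interaction contrasts were not simulated.

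Alternatives were RLE scaling, no low-count filter, a minimum mean of 1 CPM, DESeq2 1.42.0, limma-voom with quality weights, only the compared libraries, a block for the replicate number, 1 surrogate variable from sva 3.50.0, a threshold of 0.10, and leaving out each library in turn. Replicate numbers did not pair the libraries: of 18 pairs with a shared number, 3 correlated above 0.1, and 1 of 20 libraries matched its own number best. Processed pseudogene sequences were aligned to transcripts with BLAST to find near-identical copies. No library was left out of the main comparisons.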

Results

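Gene expression was measured in the cortex of 5xFAD mice, which carry human transgenes with familial Alzheimer's disease mutations and deposit amyloid. Abca7, a lipid transporter gene whose human counterpart is an Alzheimer's disease risk gene, was either wild type (control) or carried a knocked-in substitution (KI). Each genotype was sampled at 3 and at 10 months with 5 libraries per group, 20 in all, and the study asked how the substitution bears on amyloid pathology and the brain's immune response. Library depth ran from 42896149 to 57447015 counts, and 19623 genes were tested. Age was the main axis of variation: the first principal component held 22.7% of the variance, with all 10 libraries from 3-month animals between 16 and 29.8 and all 10 from 10-month animals between -42.1 and -11. The second held 14.4% of the variance, with KI replicate 3 at 3 months at 55.2.

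Abca7 itself (chromosome 10, 79996494 to 80015572) did not differ detectably in level between genotypes. At 3 months it stood at 25.4 ± 4.88 CPM in KI and 28.2 ± 1.38 CPM in control (SD, n = 5 each, exact permutation p = 0.27). At 10 months the levels were 24.1 ± 4.08 and 27.04 ± 4.33 CPM (SD, n = 5 each, exact permutation p = 0.286). App, the amyloid precursor gene, did not differ detectably between genotypes at 10 months, at 1557 ± 89.3 CPM in KI and 1567 ± 141 CPM in control (SD, n = 5 each, exact permutation p = 0.929). The counts do not say how far transgene reads are held in the mouse genes App and Thy1. Thy1, whose promoter drives the 5xFAD transgenes, stood at 1981 ± 262 CPM at 10 months against 1634 ± 134 CPM at 3 months in control (SD, n = 5 each, exact permutation p = 0.0476). In KI it stood at 2309 ± 356 against 1631 ± 137 CPM (SD, n = 5 each, exact permutation p = 0.00794).

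The sex and dissection of the libraries were read from marker genes. KI replicate 5 at 10 months held 54206 counts of Xist, the RNA of the inactive X chromosome, and 1 count of the Y-linked Ddx3y, although the protocol speaks of male mice. The other 19 libraries held at most 218 Xist counts and at least 2382 Ddx3y counts. Markers of thalamus, which lies next to cortex, had a score above 0 in 5 of 5 KI libraries and 2 of 5 control libraries at 3 months, and in 0 of the 10 libraries at 10 months. Shox2, a thalamic transcription factor, passed 50 counts in the same numbers of libraries: 5 in KI and 2 in control at 3 months, and 0 at 10 months. Ttr, a marker of choroid plexus, ran from 761 to 101020 counts across libraries.

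At 3 months, which asks what the substitution does while pathology is young, KI cortex differed from control at 5 genes, of which 4 lie on chromosome 10, the chromosome of Abca7. Tdg, a thymine DNA glycosylase of base excision repair and DNA demethylation (chromosome 10, 82629828 to 82650799), rose 3.22-fold, from 8.14 ± 0.406 to 26.2 ± 1.24 CPM (SD, n = 5 each). Cfap54, which encodes a protein of motile cilia (chromosome 10, 92775619 to 93081618), fell by 1.42 ± 0.13 on the log2 scale, from 47.2 ± 2.15 to 17.6 ± 3.33 CPM. Genes of cholesterol synthesis were higher as a group in KI, each by a small amount.

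Adjusted p from edgeR was 7.2e-07 for Tdg and 2.8e-06 for Cfap54. The other 3 calls fell outside the rule for named genes and were chosen after their values were seen. The processed pseudogenes Gm9855 (chromosome 10, 42054113 to 42055306) and Gm15920 (chromosome 5, 130188395 to 130188796) fell by 6.07 ± 0.26 and 2.89 ± 0.14 on the log2 scale, with adjusted p of 5.57e-12 and 2.74e-11. The uncharacterised gene 1190007I07Rik (chromosome 10, 82619851 to 82623228) rose by 0.80 ± 0.14 (adjusted p = 0.0428). Gm9855 is 99.2% identical to Tdg over 1194 bases, and Gm15920 is 99.5% identical to Ndufa12, a complex I subunit gene, over 402 bases, so how reads were shared out between them is uncertain. Gm9855 also matches the pseudogenes Gm5597 (99.2% over 1193 bases) and Tdg-ps (Gm5806 in the deposited symbols, 98.9% over 1194 bases). The summed counts of Tdg and Gm9855 were 1.69 times as high in KI as in control (exact permutation p = 0.00794). The sum of Ndufa12 and Gm15920 was 0.824 times that of control (exact permutation p = 0.00794), while Ndufa12 alone stood at 44.7 ± 4.5 against 39.0 ± 1.04 CPM (exact permutation p = 0.0317). Tdg overlaps Glt8d2, a further source of doubt because the strand setting of the counting is unknown.

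Among the 10 genes of smallest unadjusted p, 8 beyond Tdg and Cfap54 did not pass the adjusted test at 3 months. Emp2, a tetraspan membrane protein gene, had a log2 fold change of 0.31 ± 0.06 (adjusted p = 0.0926). Inhba, the gene of an activin subunit, had -0.68 ± 0.14 (adjusted p = 0.22), and Txnrd1, the cytosolic thioredoxin reductase on chromosome 10, had -0.21 ± 0.05 (adjusted p = 0.327). Wipf3 had -0.42 ± 0.09, the nicotinic receptor subunit gene Chrna6 0.69 ± 0.16, and the viral receptor gene Pvr 0.35 ± 0.09. The spliceosome gene Snrpf had 0.36 ± 0.09 and the clock gene Cry1 had -0.37 ± 0.09, both on chromosome 10, with adjusted p of 0.653 each.

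In the cholesterol synthesis list, 24 of 25 members lay above 0 at 3 months, with a median log2 fold change of 0.16. Camera gave an adjusted p of 3.6e-13, and the call held with an estimated correlation (adjusted p = 0.0283). Over all genes tested 0 members passed in edgeR, and 7 passed adjusted over the list alone. Insig1, which holds the sterol-sensing SREBP complex in the endoplasmic reticulum, had 0.29 ± 0.07. Fdft1, the squalene synthase gene, had 0.17 ± 0.05, and Cyp51, a sterol demethylase gene, had 0.25 ± 0.08.

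Camera called 11 further lists at 3 months, and none of them held with an estimated correlation. Immediate-early genes of neuronal activity were higher in KI at 28 of 30 members, with Fos at 1.36 ± 0.39 and Nr4a3 at 0.57 ± 0.16 (camera adjusted p = 3.6e-13; adjusted p = 0.266 with an estimated correlation). Thalamic markers were higher at 11 of 11 members (camera adjusted p = 2.18e-09; adjusted p = 0.143 with an estimated correlation), with Tnnt1 at 1.16 ± 0.38 and Tcf7l2 at 0.76 ± 0.29. Meningeal fibroblast markers had a median of 0.31 (adjusted p = 0.399 with an estimated correlation) and erythrocyte genes one of -0.77 (adjusted p = 0.207 with an estimated correlation). Among immune lists, interferon response genes had a median of 0.15 (camera adjusted p = 0.000174), antigen presentation genes 0.21 (0.00204) and border macrophage markers 0.26 (0.0018). With an estimated correlation their adjusted p was 0.638, 0.638 and 0.521. Reactive astrocyte genes had a median of 0.15, complement genes 0.16, disease-associated microglia (DAM) genes 0.05 and striatal markers -0.14, with adjusted p of 0.638, 0.638, 0.735 and 0.743 with an estimated correlation.

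Against the 5 called genes, 745 genes had an unadjusted p under 0.05 at 3 months, where 981 would be expected by chance alone. DESeq2 and limma-voom each called 12, and 0 were called once chromosome 10 genes and both pseudogenes were not counted. The call of 1190007I07Rik was lost without any single library except control replicate 10 or KI replicate 4, with adjusted p up to 0.246.

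**Figure D1:**
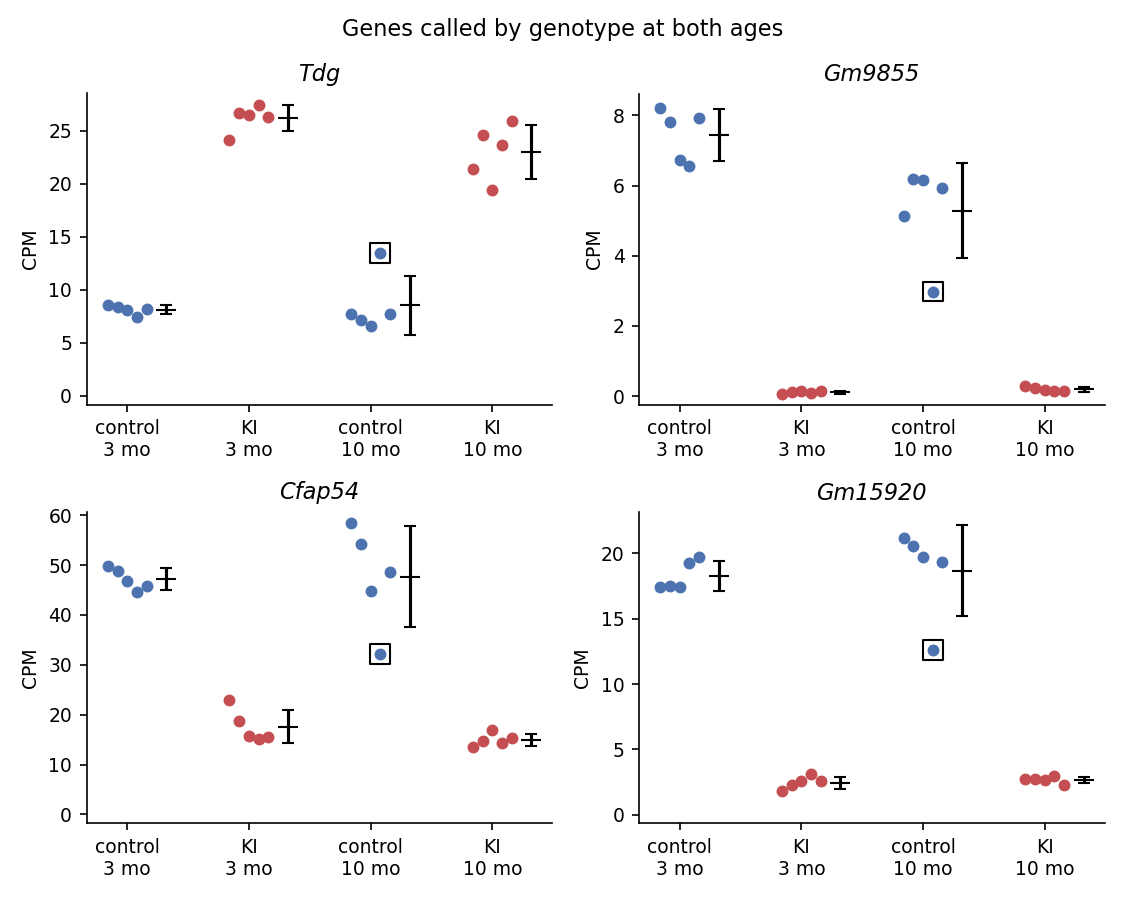
CPM of Tdg, Gm9855, Cfap54 and Gm15920 in each library, by genotype and age, with the mean and SD of each group of 5. The square marks control replicate 9 at 10 months, which stood at 13.5 CPM of Tdg, between the other control and the KI libraries.

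At 10 months, which asks about the substitution once amyloid is advanced, 12 genes differed, 7 higher and 5 lower in KI. The chromosome 10 genes stood apart again. Tdg rose 2.69-fold, from 8.52 ± 2.82 to 22.99 ± 2.58 CPM, and Cfap54 fell by 1.67 ± 0.13 on the log2 scale, from 47.7 ± 10.1 to 15.0 ± 1.26 CPM (SD, n = 5 each). Sterol genes now passed singly: Insig1 rose 1.41-fold, from 82.5 ± 8.76 to 116.3 ± 3.3 CPM, and Acat2, the gene of a cytosolic acetyl-CoA thiolase, rose 1.26-fold. Genes of the microglial response to plaques were higher in KI as groups at camera's preset correlation. With an estimated correlation these group calls were lost, and none of the genes passed singly.

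Adjusted p from edgeR was 8.7e-06 for Tdg, 2.31e-07 for Cfap54, 0.00225 for Insig1 and 0.0258 for Acat2. Nsdhl, a sterol dehydrogenase gene, rose by 0.32 ± 0.06 (adjusted p = 0.0497) and Fdft1 by 0.26 ± 0.05 (adjusted p = 0.0452) on the log2 scale. Fdft1 overlaps Ctsb, a lysosomal protease gene, so its counts are uncertain. Rreb1, a zinc finger transcription factor gene, fell by 0.44 ± 0.08 (adjusted p = 0.0452).

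Outside the rule for named genes, 5 more called genes were chosen after their values were seen. Gm9855 fell by 4.74 ± 0.24, Gm15920 by 2.80 ± 0.14 and 1190007I07Rik rose by 0.95 ± 0.14 on the log2 scale. Hal, the histidine ammonia-lyase gene (chromosome 10, 93488768 to 93519304), had 12 to 34 counts per library in control and 0 to 4 in KI (adjusted p = 0.00225). Asb10 rose by 1.05 ± 0.19 from a low level, 1.19 ± 0.209 to 2.48 ± 0.368 CPM. The sum of Tdg and Gm9855 was 1.68 times that of control (exact permutation p = 0.00794) and the sum of Ndufa12 and Gm15920 0.883 times (exact permutation p = 0.0159). All 5 calls of the 3 month comparison were called at 10 months in the same direction.

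In cholesterol synthesis, 21 of 25 members lay above 0 at 10 months (median 0.20), 4 of them called over all genes and 11 adjusted over the list alone. Camera gave an adjusted p of 5.09e-14, which held with an estimated correlation (adjusted p = 0.0214). Beyond the called genes, Stard4, a sterol carrier gene, had 0.33 ± 0.08, Msmo1 0.31 ± 0.08 and Fdps 0.29 ± 0.08, whereas the regulator gene Srebf2 had -0.02 ± 0.13. The list score was 0.21 ± 0.04 in KI and 0.02 ± 0.07 in control (SD, n = 5 each, exact permutation p = 0.00794, adjusted over the lists p = 0.286).

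DAM genes, switched on in microglia around plaques, were higher in KI at 34 of 36 members at 10 months, with a median log2 fold change of 0.25. Camera gave an adjusted p of 2.05e-13, and the call was lost with an estimated correlation (adjusted p = 0.128) but held in fry (adjusted p = 0.0358). Of them 0 passed over all genes and 14 adjusted over the list alone. Trem2, the lipid-sensing microglial receptor gene, had 0.42 ± 0.13 (adjusted p = 0.372), its adaptor Tyrobp 0.49 ± 0.13 (adjusted p = 0.305), and the protease gene Ctsd 0.33 ± 0.09 (adjusted p = 0.299). Dkk2, a Wnt pathway antagonist gene, had 0.86 ± 0.21 (adjusted p = 0.21). The DAM score was 0.98 ± 0.22 in KI and 0.66 ± 0.13 in control (SD, n = 5 each, exact permutation p = 0.0317, adjusted over the lists p = 0.428). Without KI replicate 5, the library with high Xist, the exact permutation p was 0.0556.

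Plaque-induced genes, a set of microglial and astrocytic genes that follows amyloid load, were higher in KI at 50 of 53 members (median 0.17), with 0 called over all genes and 13 adjusted over the list alone. Camera gave an adjusted p of 1.4e-14, and the call was lost with an estimated correlation (adjusted p = 0.254) and in fry (adjusted p = 0.112). Gusb, a lysosomal glucuronidase gene, had 0.31 ± 0.08 and Ctsh, a cathepsin gene, 0.47 ± 0.12. Genes of phagosome and lysosome had a median of 0.15 (camera adjusted p = 5.39e-07; adjusted p = 0.254 with an estimated correlation), with Npc2, a cholesterol carrier gene of the lysosome, at 0.23 ± 0.07. The DAM list, the plaque-induced list and the phagosome and lysosome list share members, among them Ctsd and Cd68. Their calls are not independent, here or in the other comparisons. Homeostatic microglial markers had a median of 0.09 (camera adjusted p = 0.00895; adjusted p = 0.562 with an estimated correlation), with Fcrls at 0.77 ± 0.18. Border macrophage markers had a median of 0.33 (adjusted p = 0.562 with an estimated correlation).

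Other lists called by camera at 10 months were not called with an estimated correlation. Nuclear genes of oxidative phosphorylation had a median of 0.07 and ribosomal protein genes one of 0.07, with adjusted p of 0.69 and 0.723 with an estimated correlation. Oligodendrocyte precursor markers had a median of -0.10, endothelial markers -0.11, immediate-early genes -0.13, striatal markers -0.12 and choroid plexus markers, with 0 of 16 members above 0 and the largest list median of this comparison, -0.91. Their adjusted p was 0.254, 0.562, 0.723, 0.733 and 0.756 with an estimated correlation. Gpr17, a gene of maturing oligodendrocyte precursors, had -0.48 ± 0.15, Cldn5, a tight junction gene of endothelium, -0.52 ± 0.17, and Homer1, a scaffold gene of the synapse, -0.40 ± 0.12, and none of them passed.

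At 10 months 1543 genes had an unadjusted p under 0.05, where 981 would be expected by chance alone. Calls numbered 58 in DESeq2, 75 in limma-voom and 7 when only the compared libraries were fitted; 6 remained when chromosome 10 genes and both pseudogenes were not counted, and 7 were called without control replicate 6, 9 or 10 or without KI replicate 3. Leaving out any 1 of the 10 libraries ended the calls of Fdft1 (adjusted p up to 0.307) and Nsdhl (up to 0.255), any but KI replicate 7 that of Rreb1 (up to 0.174), any but KI replicate 4 that of Asb10 (up to 0.174), and any but control replicate 8 or KI replicates 5 and 6 that of Acat2 (up to 0.234).

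**Figure D2:**
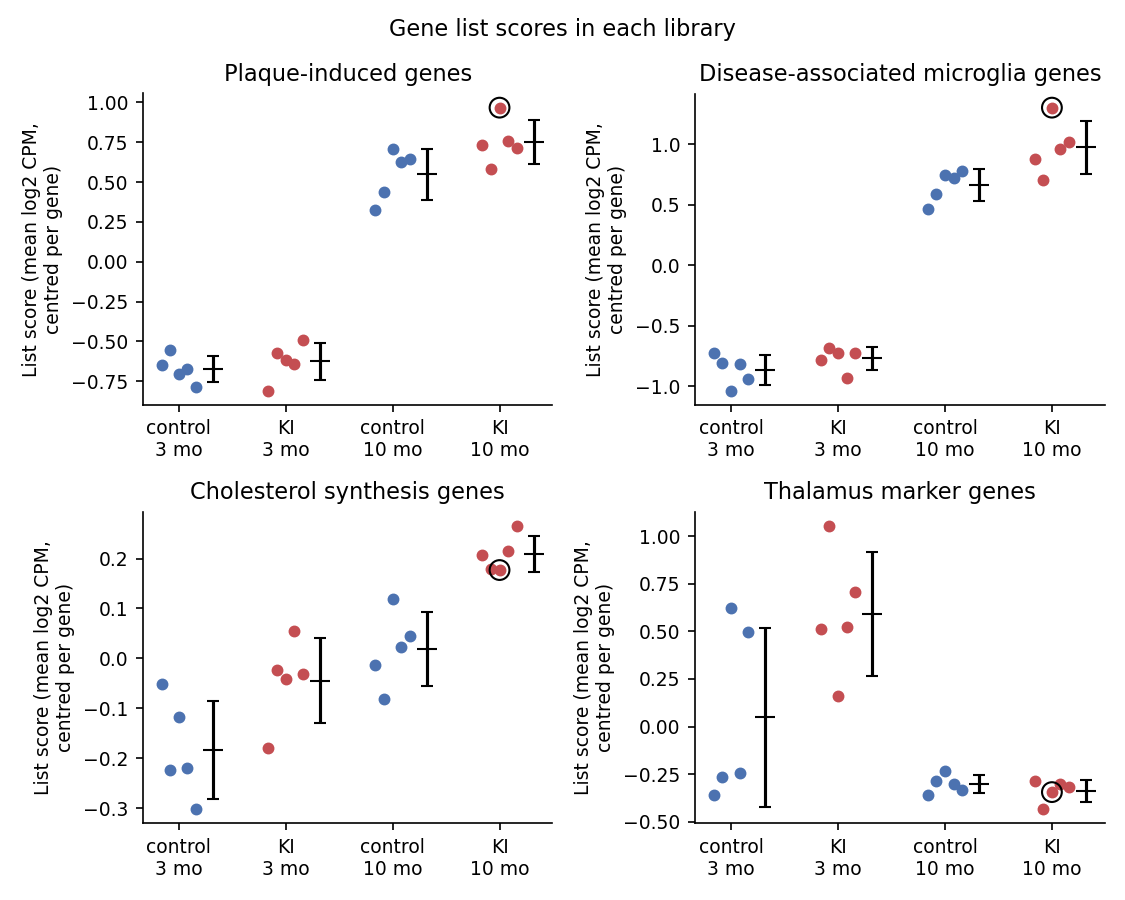
Score of 4 gene lists in each library, by genotype and age, with the mean and SD of each group of 5. The circle marks KI replicate 5 at 10 months, the library with 54206 Xist counts.

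Averaged over both ages, 10 KI against 10 control libraries, the genotype effect took in 15 genes, 9 higher and 6 lower. On chromosome 10 these were Tdg (1.56 ± 0.10 on the log2 scale), 1190007I07Rik (0.87 ± 0.10), Cfap54 (-1.55 ± 0.09), Txnrd1 (-0.20 ± 0.03), Gm9855 (-5.40 ± 0.18) and Hal (adjusted p = 7.61e-05; 0 to 4 counts per KI library), and Gm15920 had -2.85 ± 0.10. In cholesterol metabolism, Insig1 rose by 0.39 ± 0.05 (adjusted p = 0.000355), Nsdhl by 0.25 ± 0.04, Acat2 by 0.23 ± 0.04 and Fdft1 by 0.22 ± 0.04. Chrna6 rose by 0.64 ± 0.11 (adjusted p = 0.0202) and Ctxn3, a cortexin gene, by 0.35 ± 0.07 (adjusted p = 0.0404), while Inhba fell by 0.66 ± 0.10 (adjusted p = 0.00357). Abca7 had -0.16 ± 0.09 (adjusted p = 0.831).

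Cholesterol synthesis was the 1 list of 36 whose averaged call held with an estimated correlation (adjusted p = 0.00285), of 18 called by camera, with 23 of 25 members above 0, 5 called over all genes and 14 adjusted over the list alone. Its score also differed by genotype when labels were permuted within each age (exact permutation p = 0.000378, adjusted over the lists p = 0.0136). That test was not in the plan. In the exact permutation tests of 5 against 5 libraries, the score gave an adjusted p of 0.321 at 3 months and 0.286 at 10 months. DAM genes lay above 0 at 35 of 36 members (median 0.15, camera adjusted p = 2.32e-11), a call lost with an estimated correlation (adjusted p = 0.145). Oligodendrocyte precursor markers lay above 0 at 1 of 13 members (median -0.05, camera adjusted p = 0.00565; adjusted p = 0.145 with an estimated correlation). Myelin genes had a median of 0.06 (camera adjusted p = 0.031; adjusted p = 0.665 with an estimated correlation).

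Averaged over ages, 1280 genes had an unadjusted p under 0.05, where 981 would be expected by chance alone. Averaged counts of calls were 47 in DESeq2, 58 in limma-voom, 37 with a surrogate variable, 31 at a threshold of 0.10, and 8 without counting chromosome 10 genes and both pseudogenes. Of the 15 calls, 10 were kept whichever library was left out. Leaving out control replicate 7, 9 or 10 or KI replicate 4 of 10 months, or KI replicate 5 of 3 months, ended the calls of Ctxn3, Acat2, Chrna6 and Nsdhl together (adjusted p up to 0.123, 0.137, 0.0761 and 0.0647). Chrna6 was also lost without KI replicate 3 of 10 months or control replicate 10 of 3 months, and Nsdhl without control replicate 7 of 3 months. Acat2 was kept only without control replicate 8 or KI replicate 5 or 6 of 10 months or control replicate 6 or 8 or KI replicate 3 of 3 months, and Ctxn3 only without control replicate 8 or KI replicate 6 or 7 of 10 months or control replicate 9 or KI replicate 6 of 3 months.

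**Figure D3:**
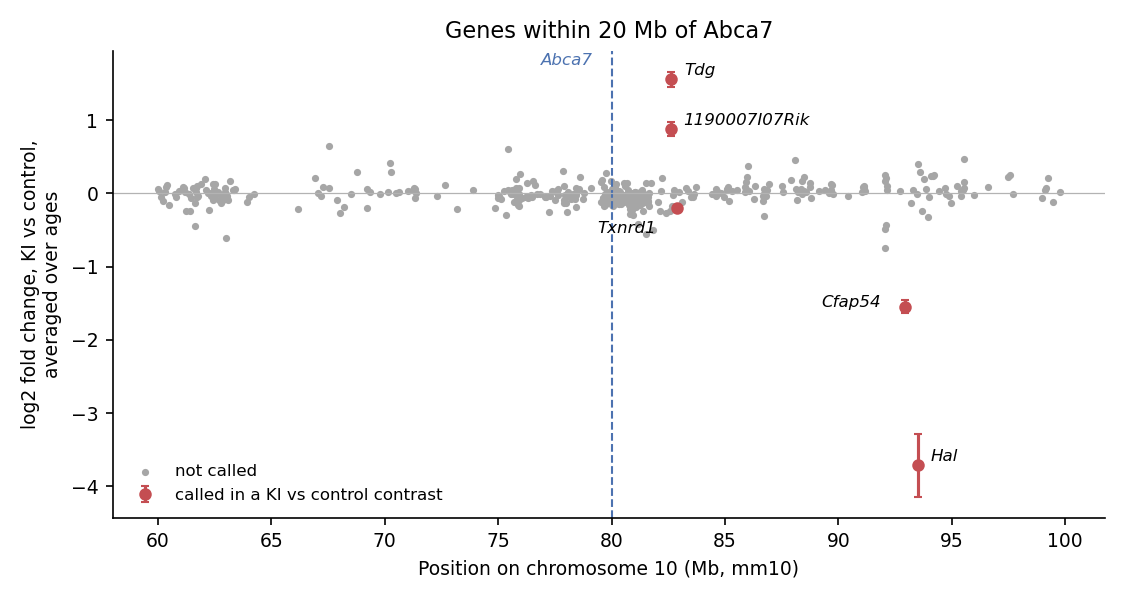
Log2 fold change between KI and control, averaged over ages, of tested genes within 20 Mb of Abca7 on chromosome 10, by position, with bars of 1 SE for called genes. Tdg and 1190007I07Rik lay above 0, and Txnrd1, Cfap54 and Hal below.

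From 3 to 10 months, genes of activated microglia and astrocytes rose in control cortex. In all, 799 genes changed, 729 higher and 70 lower. Every library came from 5xFAD cortex, so ageing cannot be told apart from advancing amyloid in either genotype. Thalamic scores were above 0 in 2 control libraries at 3 months and in 0 libraries at 10 months. Whether that difference bears on the counts was not tested. Cst7, the gene of cystatin F and a marker of plaque-associated microglia, rose 34.9-fold, from 0.934 ± 0.491 to 33.2 ± 6.82 CPM (SD, n = 5 each). Itgax, which encodes the integrin CD11c, rose 25.1-fold, Clec7a, the gene of the pattern receptor dectin, 18.1-fold, and Ccl3, a chemokine gene, 15.2-fold. Gfap, the astrocytic intermediate filament gene, rose 4.46-fold. Declines were fewer, and 5 of the 70 passed 2-fold, against 308 of the 729 increases. Among the declines were Tnc, an extracellular matrix gene, Homer1 and, with a large fold, Shox2.

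By edgeR, the adjusted p was 2.53e-09 for Cst7, Ccl3 and Gfap alike. Also among the largest increases were Ctse, a cathepsin gene (4.75 ± 0.97 on the log2 scale), Hcar2, a hydroxy acid receptor gene (4.37 ± 0.45), Ly9, a lymphocyte surface receptor gene (3.63 ± 0.34), and Lilrb4, an inhibitory receptor gene (3.59 ± 0.33). The Ctse value rested largely on control replicates 9 and 10 of 10 months, with 942 and 944 counts against 44 to 64 in the other 3 and 6 to 25 at 3 months. Ly9 overlaps Cd244, Lilrb4 overlaps Gp49a and Clec7a overlaps a further annotated gene, so the counts of these 3 are uncertain. Tnc fell by 0.70 ± 0.14 (adjusted p = 0.00225), Trib2, a pseudokinase gene, by 0.57 ± 0.11 (adjusted p = 0.00174) and Homer1 by 0.48 ± 0.12 (adjusted p = 0.0211). Klhl1 fell by 0.87 ± 0.20, Vmn2r87, a vomeronasal receptor gene, by 0.97 ± 0.24, Tmem181b-ps by 0.63 ± 0.16, Fam196b by 0.67 ± 0.18, Ddx4, the vasa helicase gene, by 0.70 ± 0.20 and Plekhg4 by 0.62 ± 0.17. Shox2 (adjusted p = 0.0147) went from 400 counts over 5 libraries to 6, and control replicates 8 and 10 of 3 months, with thalamic scores above 0, held 188 and 203 of the 400. The pseudogene Rps2-ps10 went from 4 to 1026 counts and the ferritin copy Ftl2 from 24 to 1186 over 5 libraries (adjusted p = 0.0471 and 0.0473), and single libraries of 10 months still held as few as 2 and 8.

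As groups, 49 of 53 plaque-induced genes rose in control (52 adjusted over the list alone; camera adjusted p = 1.26e-95; adjusted p = 0.000364 with an estimated correlation). Of DAM genes 29 of 36 rose (32 over the list alone; adjusted p = 0.000169 with an estimated correlation), with Lyz2, the lysozyme gene, at 2.71 ± 0.16, Tyrobp at 2.23 ± 0.14 and Trem2 at 2.02 ± 0.13. Homeostatic microglial markers rose at 15 of 26 members (22 over the list alone; adjusted p = 0.000567 with an estimated correlation), with the fractalkine receptor gene Cx3cr1 at 0.86 ± 0.09. Interferon response genes rose at 28 of 38 members (34 over the list alone; adjusted p = 0.0104 with an estimated correlation), among them Trim30a (1.2 ± 0.16) and the oligoadenylate synthetase gene Oas1a (1.151 ± 0.17). Antigen presentation genes rose at 14 of 21 members (17 over the list alone; adjusted p = 0.0104 with an estimated correlation), with B2m, the MHC class I light chain gene, at 1.27 ± 0.13. Phagosome and lysosome genes rose at 19 of 34 members (26 over the list alone; adjusted p = 0.000364 with an estimated correlation), with Cd68 at 2.03 ± 0.15 and Ctsd at 1.34 ± 0.09.

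Complement genes rose at 11 of 21 members in control (13 adjusted over the list alone), with C1qa at 1.79 ± 0.17 and the receptor gene C3ar1 at 2.27 ± 0.23. Cytokine genes rose at 9 of 21 members (11 over the list alone), with Ccl4 at 3.49 ± 0.31 and Tlr2 at 2.32 ± 0.20. Both lists had an adjusted p of 0.000364 with an estimated correlation. Reactive astrocyte genes rose at 14 of 31 members (15 over the list alone; adjusted p = 0.0129 with an estimated correlation), with the protease inhibitor gene Serpina3n at 2.01 ± 0.19 and Osmr, the oncostatin receptor gene, at 1.55 ± 0.16. Cholesterol synthesis genes rose at 8 of 25 members (12 over the list alone; adjusted p = 0.0133 with an estimated correlation), with Acat2 at 0.41 ± 0.06 and Nsdhl at 0.40 ± 0.06. Genes linked to Alzheimer's disease risk rose at 11 of 39 members and fell at 0 (12 and 1 over the list alone; adjusted p = 0.0166 with an estimated correlation), with Grn, the progranulin gene, at 0.77 ± 0.11. Synapse genes had a median of -0.11 and thalamic markers one of -0.44 (adjusted p = 0.0854 and 0.286 with an estimated correlation).

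Limma-voom called 1254 genes for age in control, and 524 of the 799 calls were kept whichever library was left out. Of the named genes, Ddx4 was kept only without control replicate 7 of 3 months, Ftl2 only without replicate 10 of 10 months, Rps2-ps10 without replicate 7 or 9 of 10 months, Fam196b without replicate 6 or 10 of 3 months, and Plekhg4 without replicate 7 or 8 of 10 months or 7 of 3 months (adjusted p otherwise up to 0.153, 0.116, 0.129, 0.0931 and 0.124). Calls were lost for Klhl1 without control replicate 6 of 3 months (0.053), Tmem181b-ps without control replicate 8 or 10 of 10 months (up to 0.0578), and Vmn2r87 without control replicate 8 or 9 of 10 months or replicate 6 or 8 of 3 months (up to 0.07).

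In KI cortex 1582 genes changed from 3 to 10 months, 1110 higher and 472 lower. Microglial genes were again among the largest increases: Cst7 rose 58.1-fold, from 0.94 ± 0.5 to 53.6 ± 11.8 CPM (SD, n = 5 each), Itgax 35.9-fold, Ccl3 24.3-fold and Clec7a 22.3-fold. KI replicate 5 of 10 months, the library with high Xist, was highest for both Clec7a and Cst7. Its Clec7a level was 38.78 CPM, against 13.38 to 15.66 CPM in the other KI libraries of that age. Its Cst7 level was 71.48 CPM, against 40.14 to 57.93 CPM. The Clec7a fold in KI therefore rests in part on that library. The astrocytic gene Gfap rose 5.5-fold. Among the largest declines were genes of thalamus, a region whose marker score was above 0 in all 5 KI libraries of 3 months: Shox2 went from 1048 counts over 5 libraries to 10, and Tnnt1 fell by 1.97 ± 0.39, Prkcd by 1.74 ± 0.40 and Tcf7l2 by 1.5 ± 0.30 on the log2 scale. Both genotypes shared 580 genes called higher, where 41.2 would be shared by independent lists, and 41 lower, where 1.68 would.

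The adjusted p from edgeR was 2e-10 for Cst7, Ccl3 and Gfap. Ctse (5.32 ± 0.99), Hcar2 (5.28 ± 0.47), Ly9 (4.26 ± 0.35), Lilrb4 (3.94 ± 0.33) and Pdcd1, the gene of the checkpoint receptor PD-1 (3.87 ± 0.32), completed the largest increases on the log2 scale, with Xist. Xist had 8.43 ± 2.32 (adjusted p = 0.033), and without KI replicate 5 of 10 months it had -1.88 (adjusted p = 0.279). Other declines were Abhd12b (fell by 2.61 ± 0.45), Slitrk6, a neuronal transmembrane gene (fell by 1.99 ± 0.54), Vipr2, a VIP receptor gene (fell by 1.55 ± 0.25), Mir1188 (fell by 1.2 ± 0.28), Baiap3 (fell by 1.19 ± 0.32) and Dio3, a thyroid hormone deiodinase gene (fell by 1.17 ± 0.24). Thalamic markers fell at 9 of 11 members and 11 adjusted over the list alone (camera adjusted p = 0.0332 with an estimated correlation). Their score was above 0 in 5 KI libraries at 3 months and in 0 libraries at 10 months. Whether the other declines, or the 472 genes called lower in all, come from that difference in thalamic score was not tested. Mir1188 lies within Rian and Shox2 overlaps Rsrc1, so their counts are uncertain.

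Plaque-induced genes rose at 49 of 53 members in KI (52 adjusted over the list alone; adjusted p = 0.000959 with an estimated correlation) and DAM genes at 32 of 36 (33 over the list alone; adjusted p = 0.000393 with an estimated correlation), with Lyz2 at 2.83 ± 0.16, Tyrobp at 2.68 ± 0.14 and Trem2 at 2.68 ± 0.13. Homeostatic markers rose at 18 of 26 members (22 over the list alone; adjusted p = 0.00154 with an estimated correlation), with Cx3cr1 at 0.95 ± 0.09 and the purine receptor gene P2ry13 at 0.84 ± 0.09. Interferon response genes rose at 23 of 38 members (31 over the list alone; adjusted p = 0.0476 with an estimated correlation), with Oas1a at 1.5 ± 0.17. Antigen presentation genes rose at 11 of 21 members (13 over the list alone), a list called by camera (adjusted p = 3.78e-10) but not with an estimated correlation (adjusted p = 0.0647 with an estimated correlation). Phagosome and lysosome genes rose at 24 of 34 members (25 over the list alone; adjusted p = 0.000995 with an estimated correlation), with Ctsd at 1.59 ± 0.09.

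Complement genes rose at 11 and fell at 1 of 21 members in KI (12 and 1 adjusted over the list alone; adjusted p = 0.00238 with an estimated correlation), and cytokine genes rose at 10 of 21 (13 over the list alone; adjusted p = 0.0023 with an estimated correlation), with Ccl4 at 4.34 ± 0.33. Reactive astrocyte genes rose at 13 of 31 members (16 higher and 3 lower over the list alone; adjusted p = 0.0476 with an estimated correlation), with Serpina3n at 2.63 ± 0.19. Cholesterol synthesis genes rose at 10 of 25 members (12 over the list alone; adjusted p = 0.0235 with an estimated correlation), with Acat2 at 0.63 ± 0.06. Alzheimer's disease risk genes rose at 10 of 39 members (14 higher and 1 lower over the list alone; adjusted p = 0.0476 with an estimated correlation), with Inpp5d, a lipid phosphatase gene of microglia, at 0.99 ± 0.10. Ribosomal protein genes rose at 22 of 59 members (27 over the list alone; camera adjusted p = 1.29e-13), a call lost with an estimated correlation (adjusted p = 0.217). Immediate-early genes rose at 1 and fell at 5 of 30 members (2 and 14 over the list alone; adjusted p = 0.349 with an estimated correlation), with Nr4a3 at -1.11 ± 0.16 and Egr3 at -0.72 ± 0.18. Endothelial markers rose at 1 and fell at 3 of 19 members (2 and 4 over the list alone; adjusted p = 0.454 with an estimated correlation), with Cldn5 at -0.78 ± 0.17 and Cdh5 at -0.44 ± 0.11.

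Age calls in KI numbered 958 when only the compared libraries were fitted, 2667 with a surrogate variable and 3027 in limma-voom, and 922 of the 1582 were kept whichever library was left out. Slitrk6 lost its call without KI replicate 3, 4 or 6 of 10 months or replicate 4 of 3 months (adjusted p up to 0.0884), Baiap3 without the same libraries of 10 months or replicate 7 of 3 months (up to 0.0827), and Xist also without KI replicates 4, 5, 6 or 7 of 3 months (up to 0.0845).

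**Figure D4:**
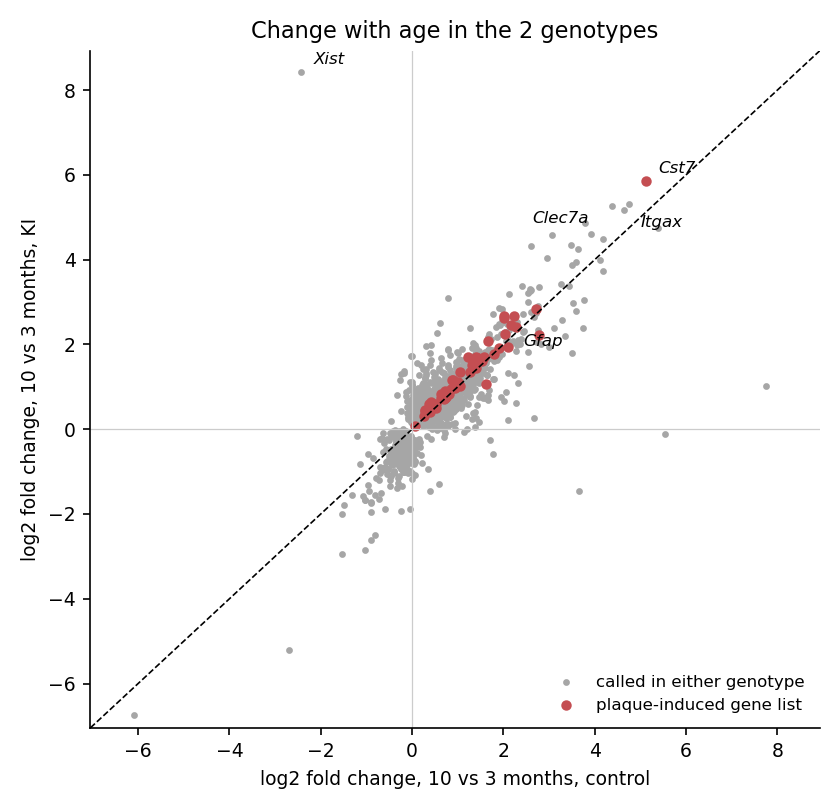
Log2 fold change from 10 against 3 months in control (horizontal) and KI (vertical) for the 1760 genes called in either genotype and the plaque-induced gene list. Of these genes 94.9% had the same sign in both genotypes, and the dashed line marks equal change.

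Whether the genotype effect differs between ages was tested by the interaction. Across the 1760 genes called for age in either genotype, among them the microglial genes Cst7, Itgax and Trem2, 94.9% had the same sign in both, with a correlation across genes of 0.811 (Pearson r; genes are not independent replicates) and a slope of KI on control of 0.944. EdgeR called 0 genes for the interaction, with a smallest adjusted p of 0.409 and 883 genes at an unadjusted p under 0.05, where 981 are expected by chance; DESeq2 and limma-voom each called 3.

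The genes of smallest p in the interaction did not pass and are given as values. Leo1, a gene of the PAF elongation complex, had a log2 difference of -0.43 ± 0.09 (adjusted p = 0.409), and Fmo2, a flavin monooxygenase gene, had 1.72 ± 0.34, at 8.57 ± 2.18 CPM in KI against 4.11 ± 1.56 CPM in control at 10 months. Arntl, the core activator gene of the circadian clock, had -0.46 ± 0.10, its repressor Cry1 0.54 ± 0.13 and the clock output gene Tef 0.33 ± 0.08. Emp2 had -0.40 ± 0.08, the potassium channel gene Kcnj2 0.66 ± 0.15, the mitochondrial folate gene Mthfd1l 0.68 ± 0.16, BC067074 -1.22 ± 0.29 and Rreb1 -0.48 ± 0.12. Abca7 had -0.01 ± 0.18 (adjusted p = 0.999). Camera called 11 lists for the interaction and 0 held with an estimated correlation, where the smallest adjusted p was 0.508; fry called 0.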

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

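The tests of the 3 patterns weighed here were chosen after the result was seen, except the test of uncalled genes near Abca7 and the counts of other splits. Libraries outlying within their group were sought in 60 measures, 240 groups of 5 in all, with a critical gap of 0.71 of the range; chance gives about 1 outlying library in 20 groups, and 15 were found.

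Genes near Abca7 made up much of the genotype effect. Of the 15 genes called in any KI against control comparison, with both pseudogenes left out, 5 lay within 20 Mb of Abca7 (odds ratio 23.2, 95% interval 6.2 to 75, Fisher's exact p = 1.08e-05), and uncalled genes of the interval had an unadjusted p under 0.05 more often than others (9.44% against 6.38%, odds ratio 1.53, 95% interval 1.06 to 2.14, Fisher's exact p = 0.0192), though neighbouring genes are not independent replicates. Reads shared with near-identical pseudogenes stay open for Tdg and Gm15920. The sums of Tdg with its 3 near-identical copies in the table and of Ndufa12 with Gm15920 differed at both ages (larger exact permutation p = 0.00794 and 0.0159). The counting program is not known, and one that drops ambiguous reads need not keep such sums, so they decide nothing. These values are consistent with variants of the chromosome 10 interval carried along with the edited allele, a candidate explanation that no genotype call could test here. A response to the knockin allele cannot be told apart from it, because all 10 KI libraries had more Tdg than every control library and none showed the allele without the interval.

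Control replicate 9 at 10 months lay between the groups at those genes, with Tdg at 13.5 CPM (other controls at most 7.74) and Gm15920 at 12.6 CPM (other controls at least 19.3). At 7 genes with separate groups, those of the interval and both pseudogenes, it lay a median fraction of 0.432 of the way from control to KI, and the highest fraction of 0.63 argued against a library that carries the label of the wrong genotype. A single copy of the KI interval could give such fractions, and the protocol speaks of heterozygous littermates, but RNA of a KI library mixed in could give them too and cannot be told apart. At 4 genes outside the interval called without this library, the mean fraction was 0.356 with an SE of 0.282, which excludes neither 0 nor the fraction inside. A first form of this test, on 10 outside genes called with this library among the controls, gave 0.025 with an SE of 0.0563 and would have argued against mixing, but it was set aside after its result was seen because those calls favour genes at which this library resembles the other controls.

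The DAM list was higher in KI at 10 months, with 34 of 36 members above 0. The library with high Xist was argued against as the whole cause, since the median log2 fold change was 0.217 without it against 0.25 with it (camera adjusted p = 1.55e-07 without it, at the preset correlation). The difference in DAM score between genotypes was 0.232 without it (exact permutation p = 0.0556) against 0.314 with it (exact permutation p = 0.0317). A higher share of microglial RNA alone stays open. The DAM minus homeostatic score was higher in KI (exact permutation p = 0.0238, and 0.0476 without that library, both unadjusted). That comparison assumes that both lists rise equally with the share, which was not tested, so it decides nothing. Spread between libraries that the members share stays open, with a camera adjusted p of 0.128 with an estimated correlation, although fry gave an adjusted p of 0.0358. An effect of the genotype on microglia therefore stays an untested hypothesis beside that spread and a higher share of microglial RNA.

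Other splits of the same libraries were counted to see how often they give as many called genes, with 100 splits per comparison, the real one included. The real split alone (1 of 100) gave as many calls for genotype at 3 months (5, highest other 1), at 10 months (12, highest other 1) and averaged over ages (15, highest other 1). The same held for age in control (799, highest other 1) and for age in KI (1582, highest other 86). Other splits mix the real groups, which widens the spread within groups and can lower their counts. These counts bear on the number of calls and do not exclude chance for any single gene. For the interaction the real count was 0 (highest other 1), which all 100 splits reach by construction, so the splits decide nothing there.

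Xist stood at 1020 CPM in KI replicate 5 at 10 months, far from at most 0.241 in its group, and at 3.92 CPM in control replicate 6 and 2.25 CPM in KI replicate 3 at 3 months. The same KI replicate 5 stood apart with a sex gene score of -4.28, Thy1 at 2930 CPM (others at most 2250), a reactive astrocyte score of 0.74, an excitatory neuron score of -0.25 and a score of genes next to Abca7 of -0.34. KI replicate 4 at 10 months had the lowest Asb10 level of its group, 1.82 CPM against at least 2.61. Control replicate 10 at 10 months had Insig1 at 97.8 CPM against at most 81.6 in the other controls. Control replicate 10 at 3 months stood apart with a hippocampus score of 0.76, an endothelial score of -0.17 and a reactive astrocyte score of -0.63.

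Camera called the genotype effect of 11 lists different between ages, and none held with an estimated correlation. Their median log2 differences were 0.143 for DAM, 0.124 for plaque-induced, 0.06 for phagosome and lysosome, 0.097 for ribosomal protein, 0.067 for oxidative phosphorylation and 0.478 for erythrocyte genes. They were -0.249 for antigen presentation, -1.821 for choroid plexus, -0.183 for endothelial, -0.54 for immediate-early and -0.435 for thalamic genes. With an estimated correlation the adjusted p was 0.508 for the immediate-early and thalamic lists and 0.757 for the other lists.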

How the results depend on the processing

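Leaving out both doubted libraries (KI replicate 5 and control replicate 9 of 10 months), leaving out X and Y genes with KI replicate 5, and not counting chromosome 10 genes with both pseudogenes were chosen after seeing the data; the other alternatives were planned. Over these alternatives 123 counts of called genes stayed within 1.5 times and 24 moved. Among values of named genes, 1984 kept their direction and side of the threshold, 250 lost and 17 gained a call, and 18 reversed. Among lists 1580 kept both, 293 lost the call and 3 reversed. RLE scaling and DESeq2 shifted the median of all genes by at most -0.0155 on the log2 scale. At 1.2-fold, simulated recovery by edgeR was at most 16%, so small folds can be missed. In the simulated genotype comparisons DESeq2 made 23 false calls among 180 at 3 months and 29 among 180 at 10 months. EdgeR made 7 among 153 and 8 among 150, and limma-voom 5 among 152 and 8 among 149. The larger counts of DESeq2 may thus hold a larger share of false calls. Fitting only the compared libraries could give no value for the averaged and interaction contrasts, and for these moves and reversals the cause was not tested, save where fewer libraries or genes enter.

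Without both doubted libraries the counts were 6 at 3 months, 8 at 10 months, 10 averaged, 768 for age in control, 1519 for age in KI and 0 for the interaction. DESeq2 called 12 genes at 3 months, 58 at 10 months, 47 averaged and 3 for the interaction. Limma-voom called 12, 75, 58 and 3, and for age 1254 in control and 3027 in KI, with Xist for age in KI at -0.26 (-1.902 in edgeR without both doubted libraries). Not counting chromosome 10 genes and both pseudogenes left 0 at 3 months, 6 at 10 months and 8 averaged. Fitting only the compared libraries gave 7 at 10 months and 958 for age in KI. A surrogate variable gave 37 averaged and 2667 for age in KI, and a threshold of 0.10 gave 31 averaged. At 10 months the DAM median of 0.251 had an adjusted p of 0.128 with an estimated correlation and 0.0358 in fry, and the plaque-induced median of 0.172 had 0.254 and 0.112.

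With a block for the replicate number, which did not pair the libraries and compares few of them within a block, the count was 4 at 10 months and 4 averaged. Abca7 under the block had 0.126 at 3 months, 0.129 at 10 months, 0.128 averaged and 0.004 for the interaction, and averaged list medians were 0.07 for erythrocyte and 0.001 for interferon response genes. Leaving out 1 library at a time gave 7 to 14 calls at 10 months, striatal medians of -0.253 to 0.057 there (above 0 without KI replicate 6), and for age in KI Xist from -1.884 to 9.819 and Abca7 from -0.182 to 0.012. For Abca7 in the interaction the range was -0.114 to 0.075, with values of 0.075 without both doubted libraries and 0.051 without X and Y genes and KI replicate 5.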

Other observations

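No test was run in this part, and the genes of this first paragraph were chosen after their values were seen. Some genes varied widely between libraries within groups. Ttr, the choroid plexus transthyretin gene, ran from 2063 to 59461 counts in control and from 2207 to 101020 in KI at 3 months, and from 1099 to 94416 and from 761 to 62117 at 10 months. Ftl2, a ferritin light chain copy, passed 50 counts in 0 of 5 control and 3 of 5 KI libraries at 3 months, and in 4 of 5 control and 2 of 5 KI libraries at 10 months. Rps2-ps10, a ribosomal protein pseudogene, passed 50 counts in 0 and 2 libraries at 3 months, and in 3 and 5 at 10 months.

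Neuronal and vascular lists moved little by age beside the microglial lists. In KI, Reln, an extracellular matrix gene of interneurons, fell by 0.46 ± 0.11 and Calb2, the calretinin gene, by 0.62 ± 0.16 on the log2 scale from 3 to 10 months, while the inhibitory neuron list had an adjusted p of 0.349 with an estimated correlation. Calb2 is also in the thalamus list, whose score was above 0 in 5 KI libraries at 3 months and in 0 libraries at 10 months. Whether its fall belongs to interneurons or to thalamic tissue was not tested. Gad1, a GABA synthesis gene, fell by 0.23 ± 0.06 in KI (adjusted p = 0.0184) and had -0.21 ± 0.06 in control (adjusted p = 0.0553). The stress gene Atf3 rose in both genotypes, by 2.30 ± 0.18 in control and 1.99 ± 0.17 in KI. Plin2, a lipid droplet gene, rose by 0.49 ± 0.10 in control and 0.48 ± 0.10 in KI, and Npc2 by 0.72 ± 0.07 and 0.85 ± 0.07.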
